A study of Mus musculus with 32 samples.

How the data were processed

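RNA of mouse lymphoma cell lines, GC B cells and splenic B cells was hybridised to 32 Agilent 2-colour arrays of 1 design, 8 per slide. Per the file headers, the scanner files were made with Feature Extraction 10.1.1.1 and hold mean and background signals as intensity and a log ratio as log10 of red (Cy5) over green (Cy3). The submitters' notes name Feature Extraction 9.1 and limma instead, so both versions are given here. The deposited series matrix holds log10 ratios that equalled the scanner's own log ratio within 0.0005 for probes above background in both channels (slope 1), with column medians from -0.083 to 0.058, so they are not centred and run as red over green. Per the labels, Cy5 held the sample and Cy3 the pool on 24 arrays, and Cy5 held PCI-32765-treated and Cy3 DMSO-treated cells on 8. No dye was swapped. The pool mixed RNA of splenic B cells of both genotypes, with and without anti-IgM, of the tumours and of GC B cells.

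Mean and background median signals were read from the scanner files and corrected in limma 3.58.1 (R 4.3.3) with normexp and an offset of 50. Loess normalisation within arrays followed, with control spots and spots the scanner software called outliers at weight 0. Both kinds were then left out, and the remaining spots of 1 probe were averaged. A probe was kept where it was well above background in either channel on at least 0.5 of the arrays of a fit. Of 55681 probes, 27235 (48.9%) had an accession in the reference list and took its symbol, which updated 2838 names, and 28446 kept the name of the array design. Each symbol was represented by its brightest probe. Of the probes, 16194 covered intervals of long non-coding RNA, and each name on the array counts as a gene here. In the lymphoma fit 21415 genes were tested, in the splenic B cell fit 22300 and in the PCI-32765 fit 17909, after 188, 15 and 1719 genes with a missing value on some sample were left out. Tables were handled with data.table (version 1.17.8), pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and figures drawn with matplotlib 3.10.9.

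Arrays of 1 sample that the series calls technical repeats were averaged before fitting, which gave 16 reference samples. The 3 GC arrays hold 1 biological and 2 technical repeats without saying which, and were averaged to 1 sample. Lymphoma lines were compared with GC, untreated and anti-IgM-stimulated B cells in 1 limma fit with 12 residual degrees of freedom. Stimulated and untreated B cells were compared in a fit of 6 samples with genotype as a term (3 residual degrees of freedom), and at 6 h alone in 4 samples. PCI-32765 was tested in a fit of 8 arrays with 1 mean per time (4 residual degrees of freedom), as the mean of 4 times, at each time, at 24 h minus 1 h, and between the 2 lines with time as a term. A moderated F test of a difference between the 4 times was added after the data were seen. Empirical Bayes moderated statistics were adjusted by Benjamini-Hochberg at 0.05 within each comparison. Blocks were fitted with duplicateCorrelation (statmod 1.5.0) where random. Profile similarity was Pearson's r across genes, with an exact two-sided sign-flip permutation test over 9 lines. Slides, where they held several groups, were fitted as a block and 1 by 1.

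A total of 26 gene lists was fixed in advance. They cover GC B cells, both types of DLBCL signature (activated B cell type and GC type), NF-kappaB targets, B cell receptor components, immediate early, cell cycle, ribosome biogenesis and MYC target, p53 target, plasma cell, resting B cell, marginal zone and B-1, precursor, DNA damage response, BCL2 family, interferon, cholesterol, glycolysis, FOXO and immunoglobulin genes. They also cover T cell, NK cell, macrophage, neutrophil, erythroid and stromal markers. Camera tested each list with a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. Named genes followed a rule, also fixed in advance: Atm and Cd3e, the 6 largest changes in each direction that passed the test with all samples on 1 side, up to 3 members of each list with the largest change among those that passed (or the largest if none did), and Myc, Malt1, Irf4, Bcl6, Prdm1, Ccnd2, Bcl2, Cd44 and Btk. Where fewer than 6 passed, others filled up by moderated t and are said not to pass. Not every gene that the rule gave is named in the text. A gene not well above background on any array of 1 group has only a bound on its fold. For it, each array of that group counted with the lowest signal well above background on that array, or with its own signal where that was higher.

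The share of spots above background in the sample channel was 45.6% to 85.5% on the drug arrays and 53.5% to 60.7% on the arrays of normal cells other than the first GC array (29.4%). It was 21.9% on the first array of line 1039. The 85.5% belonged to line 28545 at 24 h, and the other drug arrays reached at most 53.0%. Spike-in controls of known ratio correlated with their expected values at 0.909 to 0.997 except on the first GC array (0.404). The drug arrays of both lines correlated at the same time at r = 0.400, 0.711, 0.719 and 0.656 for 1, 3, 6 and 24 h across genes. Simulated data with 200 changed genes had noise drawn separately for each gene, with no failed array and no spread between stimulation times. Detection rates from them need not hold for the real data. The pipeline was tested on these simulated data. With a log2 change of 1, it found 66 of 67 in the PCI-32765 mean, 23 of 67 against GC cells and 6 of 67 in the 6-sample anti-IgM fit, and with a change of 2 it found 63 of 67 and 61 of 65 in the latter pair, with 4 to 8 false calls. Alternatives covered the background correction, the scanner's and the deposited log ratios, between-array normalisation, filters, probes, variance model, fold threshold, technical repeats, slide and line as blocks, left-out arrays and samples, and the choice of control samples. Fits without both arrays of low signal, fits within slides, and anti-IgM lists taken at 6 h were added after the data were seen.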

Results

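Gene expression was measured on 32 mouse 2-colour Agilent arrays with 62976 spots each. Of these, 24 arrays compared 1 B cell sample in Cy5 with a common RNA pool in Cy3, and 8 compared lymphoma cells treated with a drug in Cy5 with vehicle-treated cells of the same line in Cy3. The reference arrays held 9 lymphoma cell lines on 12 arrays, germinal centre (GC) B cells on 3 arrays and splenic B cells on 9 arrays. The lymphoma lines came from spleens of mice that lack the DNA damage kinase ATM and the T cell receptor subunit CD3 epsilon. The splenic B cells came from mice without CD3 epsilon, either with ATM (ATMWT) or without it (ATMKO), and were untreated or stimulated through the B cell receptor with 15 ug/ml anti-IgM. The GC B cells came from immunised mice with intact ATM. The drug was PCI-32765 (ibrutinib), an irreversible inhibitor of the B cell receptor kinase BTK, at 100 nM for 1, 3, 6 or 24 h in lymphoma lines 178119 and 28545. Technical repeats were averaged, which left 9 lymphoma lines, 1 GC sample, 2 untreated and 4 stimulated splenic B cell samples, and 8 drug arrays. The share of spots above background in the sample channel ran from 21.9% to 85.5%, and was lowest on the first array of line 1039. The first GC array had 29.4% of spots above background and correlated with the other two GC arrays at only r = 0.0938 and 0.0942 across probes, while those correlated with each other at 0.986. The number of arrays limits the precision of every value given here. Named genes were above background on at least 9 of 12 lymphoma arrays and 2 of 3 GC arrays unless a lower number is given. Changes are log2 fold changes with the standard error (SE) of the limma fit, and adjusted p values are from limma.

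Atm and Cd3e, the genes deleted in these strains, came first. Atm probe A_52_P369581 (mm9 chromosome 9, 53256167 to 53256226) read -0.71 ± 0.30 (SD, n = 9) against the pool in lymphoma lines, with lines between -1.11 and -0.23. It read -0.68 ± 0.19 (SD, n = 4) in ATMKO splenic B cells and 0.50 ± 0.23 (SD, n = 3) in ATMWT cells, GC cells included. The second Atm probe, A_52_P400509 (chromosome 9, 53245871 to 53245930), read -1.06 ± 0.38, -0.66 ± 0.27 and 0.57 ± 0.13 in the same groups. Atm signal stayed above background on 18 of 19 arrays of ATM-deficient cells and on 4 of 5 arrays of ATMWT cells. Atm was lower in lymphoma than in GC cells by limma (-1.71 ± 0.49, SE, adjusted p = 0.0408) and than in untreated B cells (-1.11 ± 0.37, adjusted p = 0.0282), and its difference from stimulated cells was -0.65 (adjusted p = 0.0743, and below 0.05 without the 3 h sample). The call for Atm was lost against GC cells in 12 of 36 alternative fits (adjusted p up to 0.416) and against untreated cells in 6 of 31 alternative fits (adjusted p up to 0.331). Cd3e (probe A_55_P2156229, chromosome 9, 44806828 to 44806887) read 0.20 ± 0.51 (SD, n = 9) in lymphoma lines, 0.98 and 0.79 in untreated ATMWT and ATMKO B cells, and -1.84 in GC cells. After anti-IgM it read 0.48, -0.26 and -0.38 at 3, 6 and 24 h in ATMKO cells and -0.14 at 6 h in ATMWT cells. Cd3e was higher in lymphoma than in GC cells (2.04 ± 0.45, adjusted p = 0.011) and did not pass the test against untreated (-0.68) or stimulated B cells (0.28). Its signal was above background on 19 of 19 arrays of ATM-deficient and 5 of 5 arrays of ATMWT cells. The Cd3e values thus run against the deletion named in the labels, and whether this probe lies in the deleted part was not tested.

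**Figure D1:**
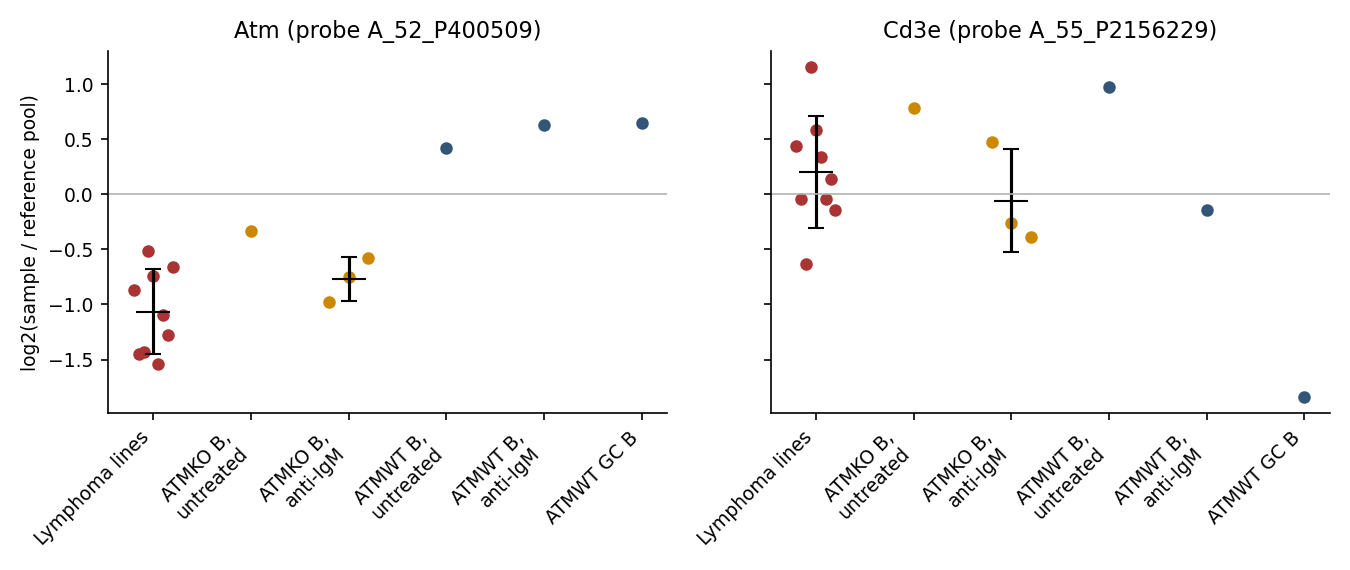
Log2 ratio of Atm (probe A_52_P400509) and Cd3e to the reference pool in each averaged sample, with black bars at the mean ± SD of groups with several samples. The 9 lymphoma lines lie between -1.54 and -0.51 for Atm, below each of the 3 ATMWT samples.

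Lymphoma lines were first set against normal GC B cells, which asks how far the tumours differ from that stage. All lines lacked ATM, whereas the GC cells had it and came from mice rather than cell lines. Tumour state, ATM genotype and growth as a cell line therefore cannot be told apart in this comparison. GC genes were lower in the tumours: Gcsam, a GC B cell adaptor, by -5.93 ± 0.68 (SE, 9 lines against 1 averaged GC sample), and Efnb1, an ephrin of GC B cells, by -4.77 ± 0.69. Genes of the activated B cell type of diffuse large B cell lymphoma (DLBCL) were higher, with cyclin D2 (Ccnd2) at 2.98 ± 0.53. The p53 target and cell cycle inhibitor Cdkn1a was higher by 3.91 ± 0.56, and the anti-apoptotic Bcl2 by 2.51 ± 0.43. Adjusted p for these 5 genes ran from 0.000167 to 0.00317 in limma, and each difference had the same sign in 9 of 9 lines.

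Of 22 measured GC genes, 9 fell and 0 rose (9 fell adjusted over the list alone), with a median of -1.33 (camera adjusted p = 1.6e-05, and 0.0267 with an estimated correlation). Plxnb2, a receptor for semaphorins, stood at -2.81, whereas Bcl6, the master repressor of the GC programme, stood at 0.02 ± 0.80 and did not pass the test. Of 16 genes of the GC-type DLBCL signature, 5 fell and 0 rose (6 fell adjusted over the list alone), median -0.64 (adjusted p = 0.0031, and 0.0317 with an estimated correlation). They included Vpreb3, a pre-B cell receptor-associated protein, at -5.33 ± 0.90, and the transcription factor Mybl1 at -1.96. Of 26 genes of the activated B cell type, 10 rose and 0 fell (12 rose and 2 fell adjusted over the list alone), median 0.96 (adjusted p = 6.0e-06, and 0.00884 with an estimated correlation). Among them were the cytokine Il10 (3.64 ± 0.92), the adhesion receptor Cd44 (1.88 ± 0.18) and Irf4, a factor of plasma cell and activated B cell programmes (1.99 ± 0.53). The call was lost for Irf4 in 5 of 36 alternative fits (adjusted p up to 0.828) and for Mybl1 in 3 of 36 alternative fits (adjusted p up to 0.655). Of 21 p53 targets, 7 rose and 1 fell (10 and 1 adjusted over the list alone), median 1.25 (adjusted p = 2.8e-05, and 0.0455 with an estimated correlation). The pro-apoptotic Pmaip1 (2.79) and Bbc3 (2.29) and the cyclin Ccng1 (2.77) were among the higher genes.

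Further lists moved only with the preset correlation. Resting B cell genes were lower (median -1.26, 4 of 20 fell, 6 adjusted over the list alone), among them the complement receptor Cr2 (-5.01 ± 0.73), the IgE receptor Fcer2a (-3.24) and the chemokine receptor Ccr6 (-2.65). Cell cycle genes (median -0.56, 0 of 24 past the test) and DNA damage response genes (median -0.51, 1 of 20 fell and 1 rose) leaned lower. Cholesterol synthesis genes (median 0.95, 3 of 19 rose), including Mvd of the mevalonate pathway (1.44), and glycolysis genes (median 1.04, 0 of 15 past the test) leaned higher. For these 5 lists the preset test gave adjusted p of 7.2e-05 to 0.01004, against adjusted p = 0.366 to 0.739 with an estimated correlation.

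The remaining B cell and pathway lists did not pass the test against GC cells, with medians of -0.18 for NF-kappaB targets, -0.59 for B cell receptor signalling components, -0.10 for immediate early genes, -0.43 for ribosome biogenesis genes, 0.51 for plasma cell genes, 0.03 for marginal zone and B-1 genes, -0.23 for B cell precursor genes, 0.16 for BCL2 family genes, -0.31 for interferon-induced genes and -0.05 for FOXO-induced genes (adjusted p from 0.0639 to 0.977). Members that passed alone included the kinase Btk (-1.16 ± 0.32), Ebi3, a subunit of interleukin 27 (2.52), the tetraspanin Cd9 (4.12 ± 0.33), the T cell checkpoint gene Ctla4 (3.31) and the antiviral Oas1a (-4.25). Markers of other cells did not shift either: T cell median 0.04, NK cell -0.31, macrophage -0.57, neutrophil -0.98, erythroid -0.33 and stromal -0.08 (adjusted p from 0.122 to 0.78). Of the immunoglobulin list, only the kappa constant gene Igkc was measured (-0.46 against GC cells, above background on 5 of 12 lymphoma arrays, not past the test).

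Large differences from GC cells outside the lists were those of Plch2, a phospholipase C (7.17 ± 1.08), Bnip3, a hypoxia-induced mitophagy receptor (5.90 ± 1.19), the fatty acid carrier Fabp4 (5.11), the tubulin Tubb6 (5.05 ± 0.94) and antithrombin (Serpinc1, 4.81 ± 0.54). Lower were Emid1 (-6.20 ± 0.61), the B cell transcription factor Bach2 (-5.37 ± 1.15, above background on 6 of 12 lymphoma arrays) and Rgs1, a regulator of G protein signalling (-5.12). In all, 2095 of 21415 genes changed, 946 higher and 1149 lower. With slide as a block 2633 changed, and within slides 2 and 4 alone, with 1 GC sample each and the spread taken from other groups, 2257 and 1312. The GC list median was -0.24 on slide 2, which held the poor GC array, -1.50 on slide 4 and -1.23 with the block. The same 3 values were 0.31, 1.17 and 0.99 for the activated type, -0.27, -0.75 and -0.65 for the GC type, and 0.67, 1.36 and 1.01 for p53 targets. Without the first GC array 3186 genes changed, Gcsam read -6.70, Efnb1 -5.53, Ccnd2 3.90 and Cdkn1a 4.67, and Ccr6 (-1.54) no longer passed, as in 16 of 36 alternative fits (adjusted p up to 0.209) in all. With only the first repeat of each sample, which left the poor array alone for GC cells, named genes that did not pass included Gcsam (-4.16), Efnb1 (-3.06), Ccnd2 (1.12), Il10 (1.47), Mybl1 (-0.43), Irf4 (0.26), Fabp4 (1.21), Serpinc1 (0.55), Ctla4 (0.73), Oas1a (-3.99) and Atm (-0.84). The GC state rests on 1 biological sample, whose spread is assumed to equal that of the other groups.

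Against untreated splenic B cells, the lymphoma lines carried more transcripts for cell division and cholesterol synthesis and fewer of resting B cells and of other blood cells. As lists they passed only with the preset correlation of camera (adjusted p = 0.136 to 0.186 with an estimated correlation). Cyclin B1 (Ccnb1) was higher by 2.62 ± 0.27 (SE, 9 lines against 2 samples), the sterol synthesis enzyme Cyp51 by 3.25 ± 0.53, and the cell cycle inhibitor and tumour suppressor Cdkn2a by 5.17 ± 0.62. The homing receptor Ccr7 fell by 7.07 ± 0.79 on the log2 scale, and the neutrophil protein S100a8 by 9.28 ± 0.62. The size for Ccr7 rested on the untreated sample, at -5.69 against ATMWT and -8.46 against ATMKO cells alone. These genes had adjusted p from 3.1e-07 to 0.000268 in limma and the same sign in 9 of 9 lines.

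Of 24 cell cycle genes, 20 rose and 0 fell (median 1.63), with DNA topoisomerase Top2a at 2.11 ± 0.24 and the mitotic checkpoint kinase Bub1 at 1.98. Of 19 cholesterol synthesis genes, 18 rose (19 adjusted over the list alone, median 2.41), with squalene epoxidase (Sqle) at 3.19 ± 0.59. Of 15 glycolysis genes, 9 rose (11 adjusted over the list alone, median 1.94), including Tpi1 (3.28), Pgk1 (3.04) and hexokinase 2 (Hk2, 2.74 ± 0.40). The array annotation places the Pgk1 probe on mm9 chromosome 3 (57906830 to 57906894), and whether it reads the Pgk1 gene itself was not tested. Of 21 p53 targets, 11 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.83), among them Cdkn1a (3.48 ± 0.42), the death receptor Fas (2.90) and Zmat3 (2.68). Of 22 GC genes, 9 rose and 4 fell (10 and 5 adjusted over the list alone, median 0.32), with the signalling regulator Rgs13 (4.79 ± 0.52) and the transcription factor Mef2b (2.97 ± 0.24) higher and Lmo2 lower (-2.47). For these 5 lists the preset test gave adjusted p of 6.6e-11 to 0.0338, against adjusted p = 0.136 to 0.211 with an estimated correlation.

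Of 20 resting B cell genes, 19 fell and 1 rose (median -3.48), led by Cr2 (-7.29 ± 0.54). Of 26 immediate early genes, 17 fell and 2 rose (median -1.78), including Fos of the AP-1 complex (-4.37 ± 0.69), the orphan receptor Nr4a1 (-4.85 ± 0.80) and Myc, a driver of growth (-2.52 ± 0.52). Against ATMWT or ATMKO untreated cells alone, Nr4a1 read -3.30 or -6.40, and Myc -1.75, which did not pass (adjusted p = 0.0772), or -3.30. NF-kappaB targets (median -1.05, 10 fell and 2 rose of 19, 12 and 2 adjusted over the list alone) and B cell receptor components (median -0.58, 11 fell and 1 rose of 26) were lower, with Btk at -1.38 ± 0.24 and the guanine exchange factor Vav3 at -2.35, while the inhibitory receptor Cd22 was higher (2.18). FOXO-induced genes (median -1.52, 10 fell and 1 rose of 18), interferon-induced genes (median -1.45, 12 fell and 1 rose of 21) and precursor genes (median -1.17, 9 fell and 1 rose of 15) were also lower. Among them were the lymphocyte egress receptor S1pr1 (-4.37), the interferon-induced Xaf1 (-4.88, above background on 7 of 12 lymphoma arrays) and Cd93 (-5.37). For these 7 lists the preset test gave adjusted p of 1.7e-09 to 0.0288, against adjusted p = 0.136 to 0.304 with an estimated correlation.

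Markers of other cells moved with these B cell groups. Of the measured members, 12 of 13 neutrophil, 14 of 14 erythroid, 10 of 11 NK cell, 14 of 17 macrophage, 13 of 19 T cell and 7 of 10 stromal genes fell. Their medians were -4.76, -4.37, -2.91, -3.04, -2.48 and -1.52, with adjusted p of 1.4e-10 to 0.0018 with the preset and adjusted p = 0.136 to 0.186 with an estimated correlation. The antimicrobial peptide Camp (-8.55 ± 0.70), alpha globin (Hba-a1, -5.50 ± 0.59), granzyme A (Gzma, -7.47 ± 0.68) and lysozyme 1 (Lyz1, -6.09) were examples. Where a gene was not well above background on any array of 1 group, only a bound is given, from the lowest detectable signal of that group, and it is open to dye bias. By that bound fibronectin (Fn1) was at least 59.4-fold and the adhesion molecule Vcam1 at least 47.1-fold lower in lymphoma, each above background on 0 of 12 lymphoma arrays, and Mgarp, a mitochondrial protein, at least 109-fold higher, above background on 0 of 4 untreated arrays.

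Beyond the lists, Plch2 (7.04 ± 0.80), Serpinc1 (6.44 ± 0.40), the Trim family member Trim12a (5.40 ± 0.29) and the membrane protein Cd109 (5.35) were higher in lymphoma. Of the activated B cell-type list, so were Il10 (3.63, and 4.58 or 2.69 against ATMWT or ATMKO cells alone), Ccnd2 (2.01) and Cd44 (1.66 ± 0.13). Bcl2 was lower (-0.93, adjusted p = 0.0352), a call lost in 10 of 28 alternative fits (adjusted p up to 0.195). Igkc stood at -1.51, and Bcl6 (1.58), Irf4 (-0.32), Prdm1 (0.25) and Malt1 (0.03) did not pass the test. Against ATMKO untreated cells alone, Irf4 was lower in lymphoma (-1.28, adjusted p = 0.033), and against ATMWT cells alone it read 0.64 (adjusted p = 0.289). Bcl6 passed in some alternative fits, such as that without line 1007 (1.71, adjusted p = 0.0329). In all, 7670 of 21415 genes changed, 3147 higher and 4523 lower. With slide as a block 7372 changed, and within slides 2, 3 and 4 alone 3258, 540 and 3658. Each slide held 1 untreated sample, so the spread within slides came from other groups, mainly the lymphoma lines, and these counts carry no spread of untreated cells. On those slides and with the block, the cell cycle median was 1.30, 1.77, 1.85, 1.66, the cholesterol median 2.49, 2.08, 2.33, 2.43, the immediate early median -1.39, -1.78, -1.95, -1.87 and the erythroid median -4.42, -4.31, -4.96, -4.71. Without the ATMKO or the ATMWT untreated sample the count was 4577 or 4581, and Malt1 and Prdm1 also changed sign in 1 of those fits. Pairs of a lymphoma array and an untreated array correlated at r from -0.488 to -0.193 across probes, with the dye orientation stated by the labels and the same throughout.

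Lymphoma lines were next set against B cells stimulated with anti-IgM, which asks whether the tumours resemble B cells with an active receptor. Even against stimulated cells, the tumours had more GC and cell division transcripts, although these lists passed only with the preset correlation (adjusted p = 0.187 to 0.195 with an estimated correlation). The GC transcription factor Bcl6 was higher by 2.32 ± 0.46 (SE, 9 lines against 4 samples), Rgs13 by 5.63 ± 0.40 and Ccnb1 by 3.46 ± 0.21. The chemokine Ccl3 (-3.23 ± 0.39) and the interferon-induced Oas1a (-4.14 ± 0.47) were lower. Adjusted p for these genes ran from 3.1e-08 to 0.000822 in limma, and each difference had the same sign in 9 of 9 lines.

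Of 24 cell cycle genes, 23 rose and 0 fell (median 2.20), with cyclin A2 (Ccna2) at 2.94 ± 0.23 and the proliferation marker Mki67 at 2.90 ± 0.28. Of 22 GC genes, 10 rose and 2 fell (median 0.47), including Mef2b (3.12 ± 0.18) and the GC confinement receptor S1pr2 (2.35 ± 0.18). Of 21 p53 targets, 13 rose and 2 fell (median 0.96), led by Zmat3 (3.26), Pmaip1 (2.80) and Cdkn1a (2.75). Of 19 cholesterol genes, 14 rose (median 1.24), and of 15 glycolysis genes, 7 rose (median 1.03), with Nsdhl at 1.68 and Tpi1 at 1.83 (2.67 without the 24 h sample, and 1.03 without the 3 h sample, adjusted p = 0.0518). The stimulated group pools unlike times for glycolysis. Its median in single ATMKO samples over untreated cells was -0.43, 0.97 and 2.50 at 3, 6 and 24 h. Counts adjusted over the list alone were equal for these 5 lists. The preset test gave adjusted p of 5.1e-15 to 0.0054, against adjusted p = 0.187 to 0.416 with an estimated correlation.

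Of 21 interferon-induced genes, 18 fell and 1 rose (median -1.85), with Xaf1 at -5.00 ± 0.55, above background on 7 of 12 lymphoma arrays. Of 19 NF-kappaB targets, 13 fell and 2 rose (15 and 2 adjusted over the list alone, median -1.30), with Tnfaip2 at -3.29 ± 0.22. Resting B cell genes (median -1.98, 13 of 20 fell), FOXO-induced genes (median -0.89, 9 of 18 fell) and precursor genes (median -1.42, 10 of 15 fell) were lower, including Ccr7 (-7.06) and the interleukin 7 receptor Il7r (-4.06, above background on 5 of 12 lymphoma arrays). For these 5 lists the preset test gave adjusted p of 3.4e-06 to 0.0221, against adjusted p = 0.1998 to 0.359 with an estimated correlation. Markers of other cells again moved with them: 12 of 13 neutrophil (median -4.17), 14 of 14 erythroid (-1.996), 10 of 11 NK cell (-1.89), 13 of 19 T cell (-2.17), 14 of 17 macrophage (-2.07) and 8 of 10 stromal genes (-1.25) fell, with adjusted p of 1.5e-09 to 0.0129 with the preset and adjusted p = 0.187 to 0.308 with an estimated correlation.

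Further single genes included Plch2 (7.09 ± 0.62), Serpinc1 (6.45 ± 0.31), Fabp4 (5.78), Ccnd2 (2.00), Cd44 (1.13) and the fucosyltransferase Fut8 (2.97 ± 0.13) on the higher side. S100a8 (-8.57), Plac8 (-7.16), the pro-apoptotic Bcl2l11 (-2.27), the plasma cell marker Sdc1 (-2.96, above background on 7 of 12 lymphoma arrays), Btk (-1.38 ± 0.18) and Myc (-1.32 ± 0.40, a call lost in 4 of 31 alternative fits (adjusted p up to 0.0619)) were lower. The NKG2D ligand H60a was at least 144-fold lower, above background on 0 of 12 lymphoma arrays. In all, 9849 of 21415 genes changed, 4533 higher and 5316 lower. With slide as a block 8659 changed, and within slides 2, 3 and 4 alone 4926, 2501 and 3024, with 2, 2 and 1 stimulated samples. On those slides and with the block, the cell cycle median was 1.83, 2.34, 2.59, 2.11, the GC median 0.30, 0.76, 1.14, 0.37, the interferon median -1.93, -1.64, -2.40, -1.87 and the NF-kappaB median -0.97, -1.33, -0.99, -1.28.

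**Figure D2:**
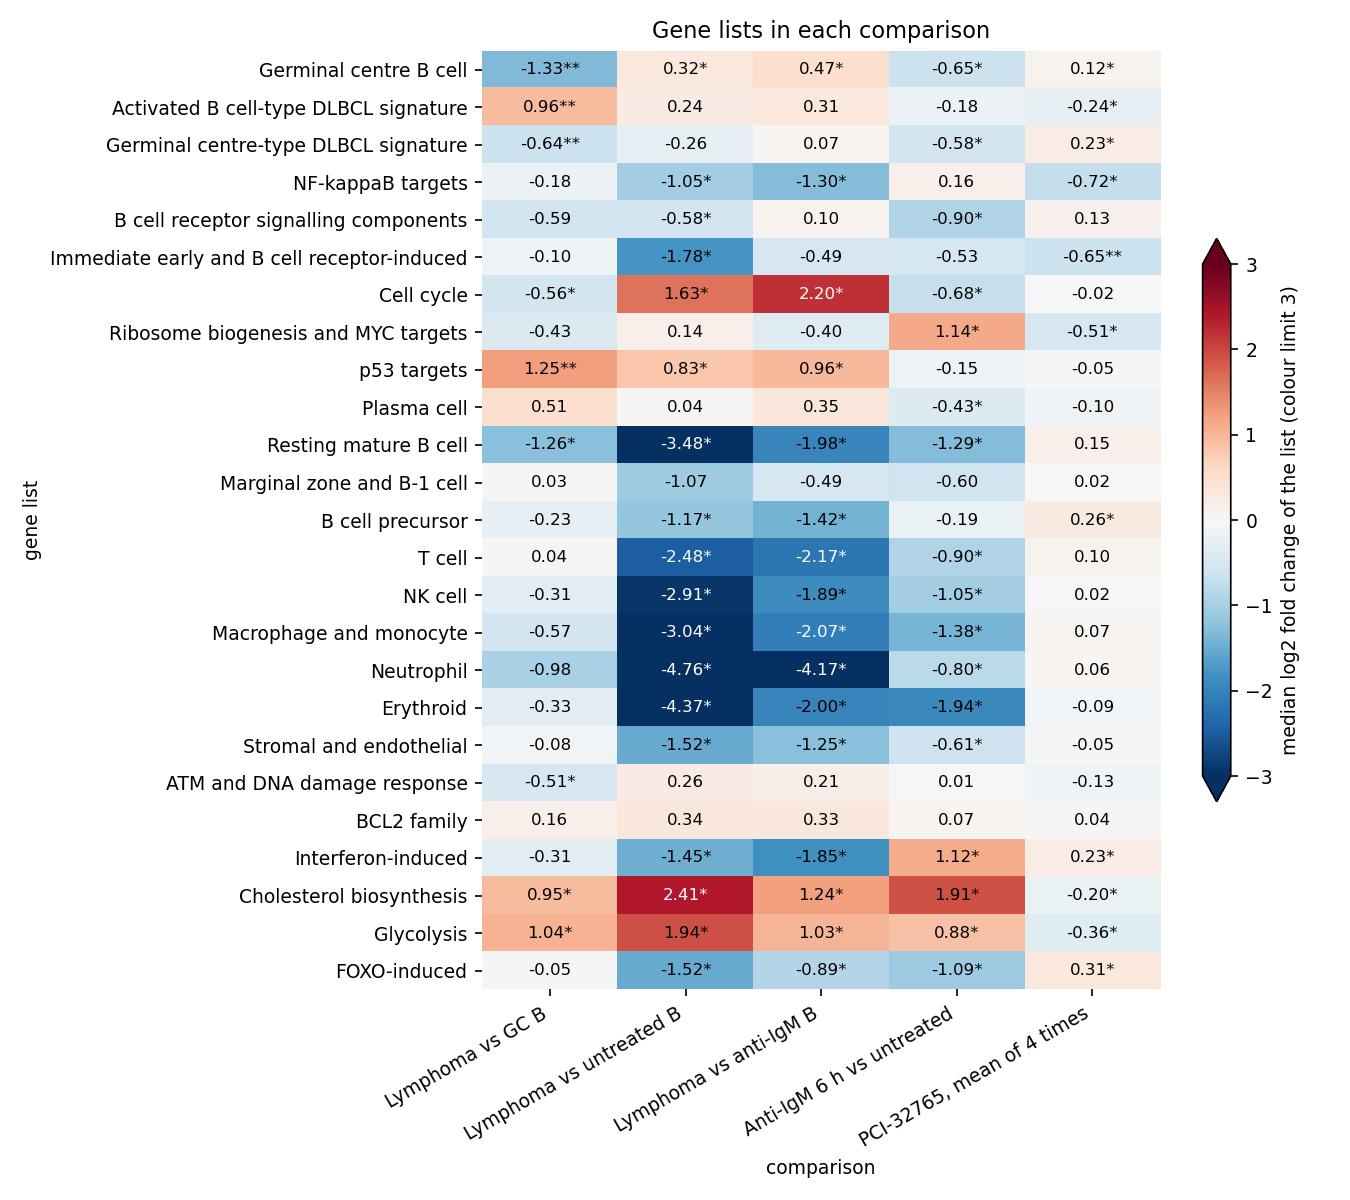
Median log2 fold change of 25 gene lists (rows) in 5 comparisons (columns), with 1 star for a preset-correlation camera adjusted p below 0.05 and a second star where it also held with an estimated correlation. The GC list reads -1.33 against GC cells and 0.47 against stimulated B cells.

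Splenic B cells stimulated with anti-IgM were set against untreated ones, to give the response to the receptor in normal cells. At 6 h, cholesterol synthesis, ribosome biogenesis and interferon-induced genes rose, and resting B cell genes fell. These lists passed only with the preset correlation (adjusted p = 0.384 to 0.416 with an estimated correlation). The isoprenoid enzyme Idi1 rose by 3.48 ± 0.17 (SE, 2 stimulated against 2 untreated samples, 1 per genotype), Sqle by 3.11 ± 0.14 and Ifit1, an antiviral protein, by 2.33 ± 0.12. Fos stood at -5.57 ± 0.13 and Cr2 at -3.23 ± 0.12, with adjusted p = 0.00222 for each in limma.

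Of 19 cholesterol genes, 18 rose (median 1.91), of 22 ribosome and MYC target genes 20 (21 adjusted over the list alone, median 1.14), of 21 interferon-induced genes 16 (17 adjusted over the list alone, median 1.12) and of 16 glycolysis genes 11, with 1 fallen (median 0.88). Examples were Hmgcs1 (3.12 ± 0.12), nucleolin (Ncl, 1.59 ± 0.11), Usp18 (2.15) and lactate dehydrogenase (Ldha, 1.93 ± 0.11). Of 20 resting B cell genes, 17 fell (median -1.29), including the quiescence factor Klf2 (-2.36 ± 0.30). Of 26 B cell receptor components, 19 fell and 1 rose (median -0.90), with the kinase Syk at -1.68 ± 0.12. Cell cycle genes fell too, 19 of 24 (22 adjusted over the list alone, median -0.68), with Mki67 at -1.40 ± 0.11, as did 14 of 19 FOXO-induced genes (median -1.09), including Txnip (-2.58), and 12 of 22 GC genes (median -0.65), including Lmo2 (-2.34). The preset test gave these 9 lists adjusted p of 6.4e-15 to 0.00276, against adjusted p = 0.384 to 0.416 with an estimated correlation.

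Markers of other cells fell alongside: 13 of 14 erythroid (median -1.94), 10 of 17 macrophage (-1.38), 10 of 11 NK cell (-1.05), 14 of 19 T cell (-0.90), 11 of 13 neutrophil (-0.80) and 9 of 12 stromal genes (-0.61), with adjusted p = 0.384 to 0.416 with an estimated correlation. NF-kappaB targets (median 0.16, adjusted p = 0.136) and immediate early genes (median -0.53, adjusted p = 0.132) did not shift as lists, although Ccl4 rose (1.38 ± 0.36) and Cd69, an activation marker, fell (-2.52 ± 0.46). The single ATMKO and ATMWT pairs gave 0.61 and 2.15 for Ccl4 and -3.53 and -1.52 for Cd69. Among BCL2 family members, Bcl2l11 (1.47) and Bcl2l1 (0.95) rose and Bcl2 fell (-1.21). Ccnd2 rose (0.57), Bcl6 fell (-0.76), and Myc (-0.58) and Irf4 (-0.39) did not pass the test. The ATMKO and ATMWT pairs gave -1.38 and 0.21 for Myc, -1.26 and 0.47 for Irf4, -1.05 and -0.47 for Bcl6, and 0.46 and 0.68 for Ccnd2. In all, 6342 of 22315 genes changed at 6 h, 2676 higher and 3666 lower, on 1 residual degree of freedom. With the ATMKO samples at 3 and 24 h included, limma called 0 of 22300 genes (1687 at an unadjusted p below 0.05), and 195 with slide as a block. The labels name the 6 h ATMKO samples as 6 h but give their treatment time as both 3 and 6 h, so the time carries that doubt.

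Whole profiles were then compared, to ask which normal B cell state each tumour line lay nearer to. Across 21415 genes, each line's log2 ratio to the pool correlated with the GC profile at a mean r of 0.271 ± 0.0261 (SD, n = 9), with the stimulated profile at -0.287 ± 0.0589 and with the untreated profile at -0.404 ± 0.0513. The difference, stimulated minus GC, was -0.557 ± 0.0714 (SD) and below 0 in 9 of 9 lines (exact two-sided sign-flip permutation test, p = 0.00391, the smallest that 9 lines allow). Genes are not independent replicates, the lines share the normal arrays, and the pool contains each of these cell types, so the states are in part centred against one another. When the controls were kept apart, the 6 h response of ATMWT cells correlated across genes with the lymphoma difference from untreated ATMKO cells at r = 0.285, and the 6 h response of ATMKO cells with the lymphoma difference from untreated ATMWT cells at r = 0.309. Both were above 0 in 9 of 9 lines. Separate untreated samples do not remove what these samples share. Erythroid (median -1.94), macrophage (-1.38) and resting B cell genes (-1.29) fell at 6 h, and the same lists fell in lymphoma against untreated cells. What such genes add to these r values was not tested.

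**Figure D3:**
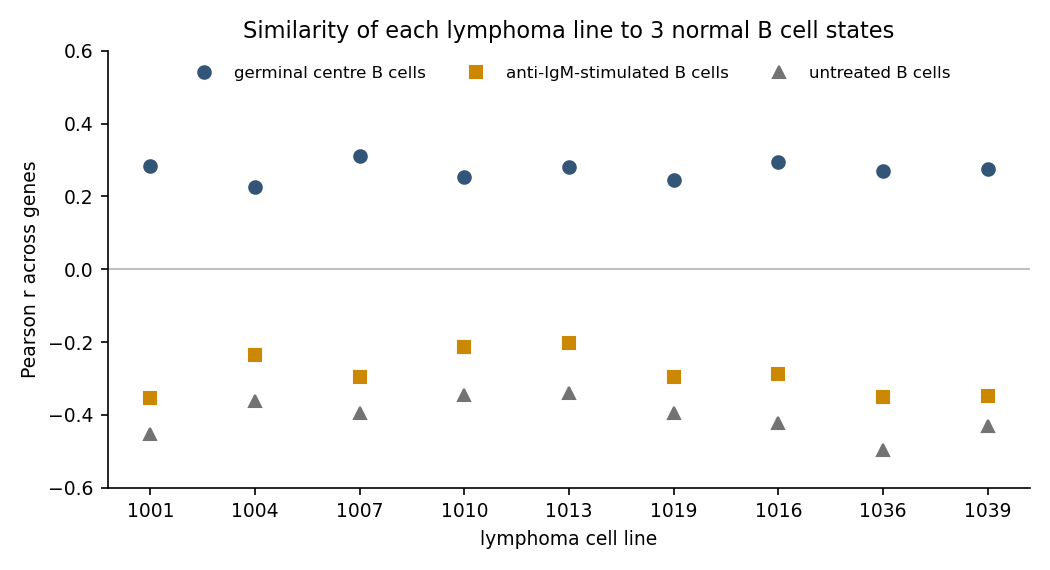
Pearson r across genes between each of the 9 lymphoma lines and 3 normal B cell profiles. For each line r was above 0 with GC B cells and below 0 with stimulated and untreated B cells, with means of 0.271, -0.287 and -0.404.

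PCI-32765 was compared with DMSO in lymphoma lines 178119 and 28545, to follow transcripts under an inhibitor of BTK. Averaged over 4 times, immediate early, NF-kappaB and MYC target genes were lower, but with an estimated correlation only the immediate early list held (adjusted p = 0.0316, against adjusted p = 0.0593 for NF-kappaB targets and 0.0593 for ribosome and MYC target genes). Egr1, an immediate early transcription factor, stood at -2.32 ± 0.071 (SE, n = 8 arrays), Tnfaip3 (A20), an NF-kappaB target, at -1.63 ± 0.075, Myc at -1.54 ± 0.058 and the NF-kappaB inhibitor Nfkbia at -1.42 ± 0.076. The phosphodiesterase Pde2a rose by 1.32 ± 0.066 and the pro-apoptotic Bmf by 0.93 ± 0.064. Adjusted p for these 6 genes ran from 1.6e-07 to 1.3e-05 in limma, and each had the same sign on 8 of 8 arrays.

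Of 16 NF-kappaB targets, 15 fell (median -0.72, adjusted p = 1.9e-14, and adjusted p = 0.0593 with an estimated correlation), including Ier3 (-1.07 ± 0.065). Of 19 immediate early genes, 15 fell (17 adjusted over the list alone, median -0.65, adjusted p = 1.2e-12, and 0.0316 with an estimated correlation), including Egr2 (-1.56 ± 0.069). Of 15 ribosome and MYC target genes, 14 fell (15 adjusted over the list alone, median -0.51, adjusted p = 6.4e-11, and adjusted p = 0.0593 with an estimated correlation), with the RNA polymerase I subunit Polr1b at -0.81 ± 0.055, the nucleolar Nolc1 at -0.74 and the transferrin receptor Tfrc at -0.71. Of 19 activated B cell-type genes, 10 fell and 2 rose (11 and 3 adjusted over the list alone, median -0.24, adjusted p = 8.5e-05, and adjusted p = 0.0593 with an estimated correlation). The lower ones included the caspase 8 regulator Cflar (-1.001 ± 0.089), Batf (-0.87 ± 0.064), Irf4 (-0.84 ± 0.057, lower on 6 of 8 arrays) and Bcl2 (-0.68 ± 0.051).

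Of 18 FOXO-induced genes, 11 rose and 0 fell (13 rose adjusted over the list alone, median 0.31), including Txnip, a brake on glucose uptake (0.78 ± 0.048), Bcl6 (0.66 ± 0.052) and Ccng2 (0.64). GC genes (6 rose and 1 fell of 16, median 0.12), GC-type genes (6 and 1 of 12, median 0.23), precursor genes (5 and 0 of 8, median 0.26) and interferon-induced genes (8 and 1 of 15, median 0.23) were higher. S1pr2 (0.69 ± 0.051), Nuggc (0.69), Vpreb3 (0.98 ± 0.051), the DNA polymerase Dntt (0.67) and Irf7 (0.59) were examples. Cholesterol genes (8 of 16 fell, 9 adjusted over the list alone, median -0.20) and glycolysis genes (4 of 6 fell, median -0.36) were lower, including Lss (-0.49) and Hk2 (-0.41). For these 7 lists the preset test gave adjusted p of 1.2e-06 to 0.0342, against adjusted p = 0.0719 to 0.567 with an estimated correlation. Within the BCR component list, the adaptor Dok3 (0.75) and Malt1, a protease of NF-kappaB signalling (0.44), rose, and Btk fell (-0.24). The pro-apoptotic Bax fell (-0.46), the plasma cell marker Sdc1 fell (-0.58, above background on 5 of 8 drug-treated samples), Cd44 did not pass the test (-0.07), and Atm stood at 0.25 ± 0.062, higher on 6 of 8 arrays, and Cd3e at -0.13.

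Of the cell type lists, none passed the preset test in the mean: T cell median 0.10, NK cell 0.02, macrophage 0.07, neutrophil 0.06, erythroid -0.09 and stromal -0.05 (adjusted p from 0.505 to 0.901). In the mean, 5810 of 17909 genes changed, 3000 up and 2810 down, of which 31 by at least 2-fold. The 8 arrays shared 1 slide, and line as a fixed block gave 5555 genes. PCI-32765 was always in Cy5, so a constant dye effect of a gene is part of its value in the mean and at each time, but cancels in the difference between times.

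The 4 times were then taken singly. At 1 h, 18 genes passed, 5 up and 13 down, led by Egr1 (-2.41 ± 0.14, SE, n = 2 lines), Egr2 (-2.13 ± 0.14), Fos (-1.66 ± 0.093), Cd69 (-1.45 ± 0.11) and Myc (-1.05 ± 0.12, limma adjusted p = 0.00657). Immediate early genes fell as a list (median -0.56, 6 of 19 fell, 11 adjusted over the list alone, adjusted p = 2.4e-13, and 0.0272 with an estimated correlation). At 3 h, 1291 genes passed (552 up, 739 down), and 16 of 16 NF-kappaB targets fell (median -1.04, adjusted p = 2.8e-25, and 0.0181 with an estimated correlation). Immediate early (10 of 19 fell), ribosome (12 of 15) and activated B cell-type genes (9 of 19) also fell, with adjusted p = 0.0155 to 0.0304 with an estimated correlation. Egr1 stood at -3.46 ± 0.14, Myc at -2.47 ± 0.12, Tnfaip3 at -2.45 ± 0.15 and Il4i1, an amino acid oxidase, at -2.60 ± 0.19, while the lipid phosphatase Plpp3 (1.17 ± 0.12) and the phosphodiesterase Pde4a (1.03 ± 0.12) rose. At 6 h, 4351 genes passed (2149 up, 2202 down), with 14 of 15 ribosome genes (median -0.94) and 14 of 16 NF-kappaB targets (median -0.92) lower, adjusted p = 0.0481 with an estimated correlation. Plscr1 (-2.30 ± 0.098) and Ctla4 (-2.03 ± 0.20) were among the lowest, and the MHC class II gene H2-Eb2 (1.59 ± 0.13) and the deubiquitinase Usp2 (1.48 ± 0.11) among the highest.

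At 24 h, 4138 genes passed (1981 up, 2157 down). Pde2a (3.00 ± 0.13), the actin-severing protein Gsn (2.38 ± 0.11), the acid phosphatase Acp5 (2.17 ± 0.12) and Vpreb3 (2.12 ± 0.10) were higher. Trib3 (-2.66 ± 0.17) and Chac1 (-2.43 ± 0.16), both known targets of the stress factor ATF4, the alanine transaminase Gpt2 (-2.30 ± 0.12) and the lactate exporter Slc16a3 (-2.22 ± 0.29) were lower. Cell cycle genes fell (13 of 17, 17 adjusted over the list alone, median -0.58), with Ccnb1 at -0.79 and the replication licensing factor Cdc6 at -0.87, and NF-kappaB targets still did (7 of 16, median -0.23). GC genes (8 rose and 1 fell of 16, median 0.57), GC-type genes (7 of 12 rose, median 0.80), BCR components (9 rose and 1 fell of 21, median 0.30) and resting B cell genes (7 of 15 rose, median 0.35) were higher. The preset test gave these 6 lists adjusted p of 1.7e-08 to 0.0027, against adjusted p = 0.126 to 0.205 with an estimated correlation. Between 1 h and 24 h the effect itself differed for 1270 genes, 612 higher and 658 lower at 24 h, led by Pde2a (2.88 ± 0.19) and Fbxw13 (2.52 ± 0.20) and by Chac1 (-2.77 ± 0.23) and Trib3 (-2.68 ± 0.24). Egr1 (1.45), Egr2 (1.77) and Fos (1.79) were less lowered at 24 h than at 1 h.

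Single arrays weighed on the counts at single times, since each time had 2 lines. Leaving out line 178119 or line 28545 at that time gave 8 or 79 genes at 1 h, 136 or 149 at 3 h and 1293 or 2667 at 6 h, and at 24 h 1451 without line 178119. The count of genes that differed between 24 h and 1 h fell to 411 and 477 without the 1 h array of line 28545 or 178119, to 506 without the 24 h array of line 178119, and to 749 and 748 without a 3 h array.

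**Figure D4:**
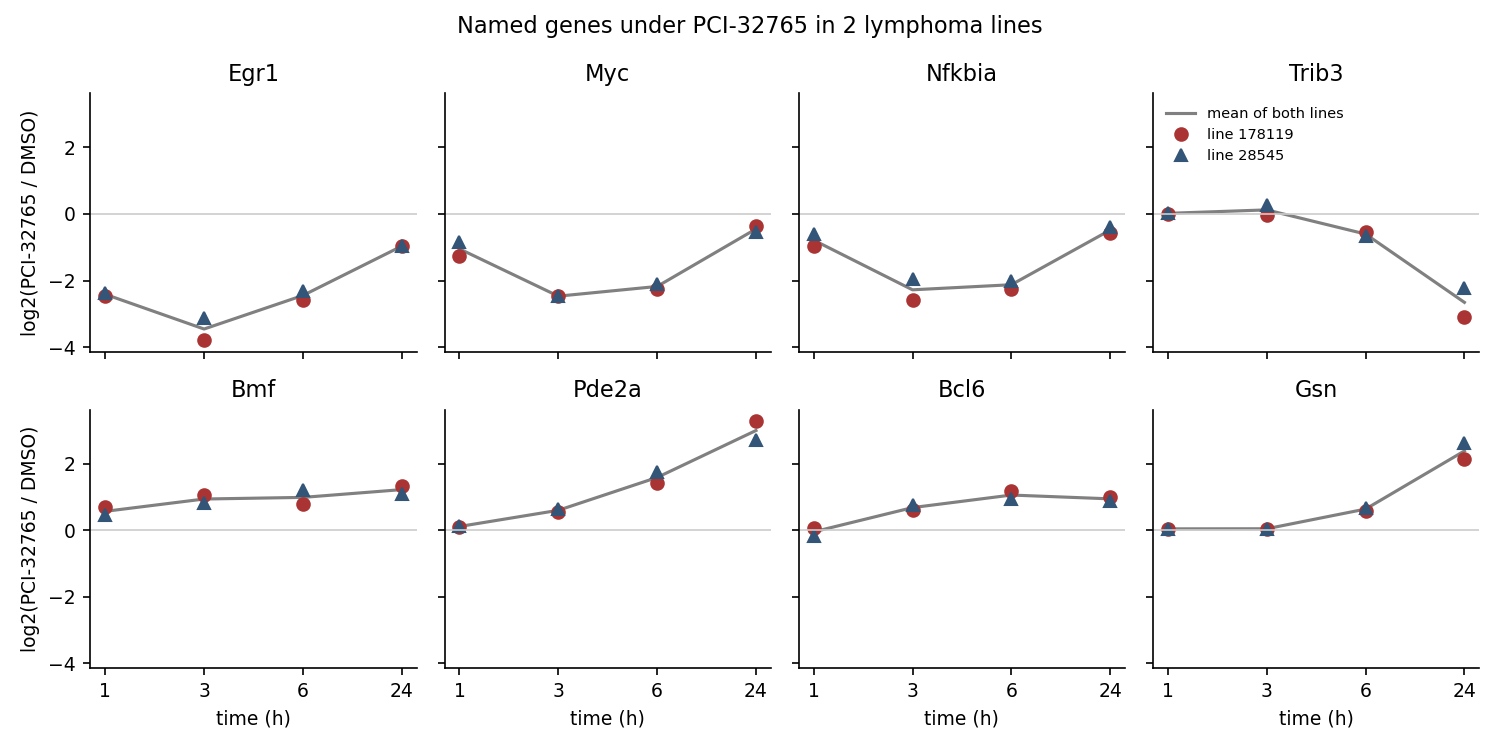
Log2 ratio of PCI-32765 to DMSO at 1, 3, 6 and 24 h for 8 genes, with 1 symbol per cell line and a line through the mean of both. Mean Egr1 reads -2.41 at 1 h and -0.97 at 24 h, whereas mean Pde2a reads 3.00 at 24 h.

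The effect of the drug was also compared between line 178119 and line 28545. Across 4 times, limma called 0 of 17909 genes different (643 at an unadjusted p below 0.05, against 895 that chance alone gives). The complement receptor Cr2 had the strongest lean to a higher effect in line 178119 (0.70 ± 0.12, adjusted p = 0.748) and the mitotic kinesin Kifc1 to a lower one (-0.71 ± 0.11, adjusted p = 0.748). Myc (-0.10), Bcl6 (0.10), Irf4 (-0.16) and Btk (-0.16) did not pass the test either.

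Genes that anti-IgM moved in splenic B cells were followed under the drug in lymphoma lines, to ask whether they moved the opposite way. Since 0 genes passed over all stimulated samples, each list took the 100 genes with the largest shift in the same direction in 4 of 4 stimulated samples. The list of lowered genes held markers of red cells (Car1, Car2), macrophages (Mrc1) and NK cells (Nkg7), and immediate early genes (Fos, Fosb, Cd69). How much of either list is a response of B cells to the receptor was not tested. Of 72 measured genes raised by anti-IgM, 38 fell and 5 rose in the mean under PCI-32765 (median -0.20, camera adjusted p = 5.0e-08, and 0.00377 with an estimated correlation). These are names on the array rather than separate genes. The lowest, at -1.70, -1.70, -1.57 and -1.54, were entries of 1 stretch of chromosome 16, and others had no gene symbol. Of 56 genes lowered by anti-IgM, 24 rose and 8 fell (median 0.15, adjusted p = 0.000716, and adjusted p = 0.0541 with an estimated correlation). At 6 h the raised genes had a median of -0.34, with 30 lower and 2 higher (adjusted p = 2.0e-08, and 0.0034 with an estimated correlation). At 3 h they had a median of -0.14, with 12 lower and 1 higher (adjusted p = 2.4e-05, and 0.00924 with an estimated correlation). The lowered genes had medians of 0.10 at 3 h (adjusted p = 0.132, and adjusted p = 0.296 with an estimated correlation) and 0.13 at 6 h (adjusted p = 0.00653, and adjusted p = 0.0958 with an estimated correlation). At 24 h both moved, the raised genes to -0.24 (25 lower, 3 higher) and the lowered genes to 0.33 (25 higher, 4 lower), with adjusted p = 0.00877 and 0.00956 with an estimated correlation. At 1 h neither list shifted (adjusted p = 0.181 and 0.181).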

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

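The tests of a dye effect, of the first GC array and of a lower share of B cells were chosen only after the results they rest on had been seen, and the other tests after the patterns but before their own values. Of 61 groups of samples examined for a single sample far from the rest, 13 had one, where chance alone gives about 1 in 20. The gene lists, comparisons and named-gene rule were set before the data were examined. For anti-IgM, the main comparison so set was that over all stimulated samples, and that at 6 h alone was an alternative.

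The averaged ratios of line 1039 stood apart from the other 8 lymphoma lines for 9 genes that were very low in all of them. Its averaged log2 ratios to the pool were -2.61 for Emid1, -2.41 for Gcsam, -5.02 for S100a8, -4.14 for Camp, -3.94 for Plbd1, -4.20 for Chil3, -3.33 for S100a9, -3.23 for Gzma and -3.65 for H60a. On its first array, which had 21.9% of spots above background, S100a8 read -1.40 and Gcsam -0.05, and on its second array -8.65 and -4.77. On the second array each of the 9 genes lay within or below the range of the other 8 lines. The averages thus stood apart through the first array alone. These 9 outliers count among the 13 groups above. Line 1007 was the highest of 9 lines for Prdm1 (2.72, others -0.60 to 0.88) and the lowest for Tnfrsf19 (-1.79, others 0.22 to 2.14). Among the 4 stimulated samples, Ear10 read 0.31 in ATMWT cells at 6 h (others -0.25 to -0.17) and Myc -1.72 in ATMKO cells at 24 h (others 0.48 to 0.65).

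The effect of PCI-32765 differed between lines 178119 and 28545 for 7 gene lists with the preset correlation of camera. Medians of line 178119 minus line 28545 were -0.0478 for the activated B cell type, -0.12 for NF-kappaB targets, -0.0756 for cell cycle, -0.0557 for ribosome biogenesis, -0.0705 for DNA damage response, -0.0999 for interferon-induced and -0.20 for glycolysis genes. Their adjusted p was 0.000192 to 0.0299 with the preset and 0.471 to 0.882 with an estimated correlation. No single gene passed in limma (0 genes, 643 at an unadjusted p below 0.05), and 0 of 72 named genes moved one way on all arrays of 1 line and the opposite way on all of the other. Of the 35 splits of the 8 arrays into 4 and 4, 32 could be fitted, and all 32 gave at least as many genes as the real split of the lines (0 genes, highest other 4). With a real count of 0 no other outcome was possible, so the splits say nothing on chance here.

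Between 24 h and 1 h the effect differed for 1270 genes and for 11 lists with the preset correlation. Medians of 24 h minus 1 h were 0.75 for GC B cell genes, 0.85 for the GC-type signature, 0.33 for B cell receptor components, 0.26 for immediate early, 0.25 for resting B cell, 0.46 for precursor and 0.22 for FOXO-induced genes. They were -0.72 for cell cycle, -0.34 for ribosome biogenesis, -0.40 for DNA damage response and -0.57 for glycolysis genes. Adjusted p was 1.5e-10 to 0.0164 with the preset and 0.109 to 0.415 with an estimated correlation.

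The first pattern weighed is the broad response to PCI-32765, which was in Cy5 on every array. If each gene's value were a constant dye effect, its effect at 1 h would equal that at later times. Over the 5810 genes called in the mean, the 1 h effect was a median 0.350 of the mean later effect (quartiles -0.00496 to 0.823), which argues against a dye effect as the whole cause. Of the 1623 called genes with a ratio above 0.75 (27.9%), 23.8% differed between the 4 times at an unadjusted p below 0.05 in a moderated F test (387 genes, 81.2 by chance), and 90 passed after adjustment, among them Egr1 (adjusted p = 0.000698) and Egr2 (adjusted p = 0.000764), which a constant dye effect forbids. For the other 1533, 26.4% of the called genes, a dye effect and an early drug effect cannot be told apart, since no dye was swapped, and a drug effect stays a hypothesis elsewhere.

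The second pattern is the first GC array, which correlated with no other array. Its spike-in controls, which do not come from the sample, correlated with their known ratios at 0.404 against 0.909 to 0.997 on the other 31 arrays, so failed hybridisation or labelling may account for it. RNA of another sample stays open: the best correlation with any other array was 0.0942, but an array that failed would match no sample, whatever its RNA. No biological explanation was tested. Without that array and the first array of line 1039, the GC, activated-type, GC-type and p53 list medians were -1.58, 1.25, -0.83 and 1.49, against -1.33, 0.96, -0.64 and 1.25 with them.

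The third pattern is the low level of genes of other blood cells in lymphoma lines. Other spleen cells in the untreated B cell samples may be the source: abundant transcripts of neutrophils and red cells had a median brightness percentile of 97.7 over 5 genes in the untreated samples. There S100a8 was at 97.7 (21.5 in lymphoma) and Hba-a1 at 98.4 (65.6), but Lyz2 only at 77.1 (40.6), and since probes differ in affinity such a percentile is a rough level that leaves this source open. A lower share of B cells alone would raise each other cell type alike, and list medians of untreated minus GC cells were 2.75 for T cells, 3.02 for NK cells, 2.57 for macrophages, 3.93 for neutrophils and 3.95 for red cells. The mice of the splenic B cells lacked the T cell receptor subunit CD3 epsilon, so whether the T cell list reads T cells there was not tested. The largest gap between these medians, 1.37, is within the spread of the lists, so a lower share of B cells stays open. So does a difference in the B cells themselves, which was not tested. The GC mean here included the poor first array. On slide 4, which held the other GC arrays, lymphoma medians against GC cells were -0.05 to 0.21 for these lists. Against untreated cells they were -5.41 for neutrophil, -4.96 for erythroid, -2.91 for macrophage, -3.05 for NK and -3.01 for T cell genes. The gap may thus be larger without the poor array, which was not tested.

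For lymphoma against anti-IgM-stimulated B cells, 1 of 100 splits drawn from the 715 possible gave as many genes as the real one. It was the real split itself (9849 genes, highest other 1244). Every other split mixes tumour lines with splenic cells, which adds the difference between them to the spread. The real split was thus favoured in advance, and the splits cannot decide on chance here.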

How the results depend on the processing

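Fits without both arrays of low signal, fits within slides and anti-IgM lists taken at 6 h were chosen after the data were seen. Of the alternatives set in advance, 270 values of the comparisons held, 44 moved and 5 values of the anti-IgM-lowered list lost their call. A count of genes held within 1.5 times the reported count, and a correlation within 1 SD over the lines. For single named genes, 12625 values kept direction and call, 749 lost the call, 17 gained one and 38 changed sign. For gene lists, 917 kept and 35 lost the call, and 0 changed sign. Of the added ones, 8 comparison values held and 1 moved, 222 gene values kept the call, 1 lost it, 2 gained it and 2 changed sign, and 132 list values kept and 1 lost it. Profile similarity stayed below 0 under all 19 alternatives (-1.15 to -0.307), and the line difference gave 0 genes in each of its 19. The deposited log ratios shifted the median of all genes by -0.129 against GC cells, the largest such shift. Arrays with few spots above background and a single GC sample limit the comparison with GC cells, and 2 lines per time limit the counts at single times. Slide could not be fitted for the PCI-32765 arrays, which shared 1 slide.

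Against GC cells (2095 genes), taking the 3 arrays as 3 samples gave 5401 genes, and taking array 1, 2 or 3 as a sample beside the mean of the others gave 3304, 5610 and 5580. Leaving out 1 sample or array gave 1813 to 3186, the highest without the first GC array, and leaving out both arrays of low signal 3303. Against untreated cells (7670) it gave 4577 to 8569, and 4581 with only ATMKO untreated cells. Over all anti-IgM times (0 genes) the 6 h samples alone gave 6342, all 16 samples in 1 fit 143, repeats as a random block 8 and slide as a block 195. A threshold of 2-fold left 4244 genes against untreated and 4096 against stimulated cells. Under it PCI-32765 had 31 genes in the mean, 10, 92, 286 and 264 at 1, 3, 6 and 24 h, and 246 at 24 h minus 1 h. Apart from that threshold, the cause was not tested.

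Without background subtraction 53 genes passed at 1 h (18 reported), the separate-control r of the ATMKO response was 0.339 and the anti-IgM-lowered list under PCI-32765 lost its call at a median of 0.0858. With an offset of 0, 30 genes passed at 1 h and 667 at 24 h minus 1 h, the separate-control values were 0.258 and 0.271, and that list had 0.0912. The scanner's log ratios gave 584 genes at 3 h, 299 at 24 h minus 1 h, a separate-control r of 0.254 and 0.0951 for that list. The deposited ratios gave 579, 297, 0.254 and 0.0627. The 50 largest genes in that list gave 0.0305. Leaving out 1 array gave 8 to 79 genes at 1 h, 136 to 1611 at 3 h, 1293 to 4873 at 6 h, 1451 to 4276 at 24 h and 411 to 1478 at 24 h minus 1 h. The cause was not tested for these.

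Changes of sign concerned genes that did not pass the test, apart from Kit, Sec11c and Mzb1. Leaving out 1 sample or array, values against GC cells ran from -2.76 to 0.59 for Kit, -0.61 to 0.11 for Myc and -0.20 to 0.16 for Bcl6. Against untreated cells they ran from -0.47 to 0.53 for Malt1, -1.28 to 0.64 for Irf4 and -0.33 to 0.82 for Prdm1, and against stimulated cells from -0.25 to 0.19 for Prdm1. For anti-IgM they ran from -0.43 to 0.21 for Atm, -2.20 to 0.21 for Myc, -1.63 to 0.47 for Irf4, -0.28 to 0.54 for Prdm1, -0.27 to 0.68 for Ccnd2 and -0.50 to 0.35 for Btk. Without both arrays of low signal, Kit read 0.40 and Myc 0.0545 against GC cells. With only the first repeat, Sec11c read -0.27 against GC cells, Prdm1 -0.0148 against stimulated cells and Btk -0.0314 under anti-IgM. With only ATMKO untreated cells, Malt1 read -0.47 and Prdm1 -0.33, and with only ATMKO stimulated cells Prdm1 read -0.0488. At 6 h alone, Btk read -0.29 and Prdm1 -0.17 under anti-IgM, and with slide as a block Btk read -0.0535. Under PCI-32765, Mzb1 read -0.0129 with the scanner's and -0.0127 with the deposited ratios. The cause was not tested for these.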

Other observations

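No test in this part was chosen only after its result was seen, and the 1 test of a hypothesis was set after the main comparisons but before its own values. Single samples of ATMKO B cells gave a time course of anti-IgM without replicates, so its values carry no test. Time in culture could not be told apart from anti-IgM in it. Medians at 3, 6 and 24 h against untreated cells were -0.43, 0.97 and 2.50 for glycolysis, -0.20, 2.02 and 0.92 for cholesterol synthesis, 0.64, 0.96 and -0.79 for ribosome biogenesis, -0.68, 1.22 and 0.21 for interferon-induced and 0.34, 0.03 and -0.25 for NF-kappaB target genes. Erythroid markers read -0.57, -1.82 and -3.53, and macrophage markers -0.63, -1.40 and 0.35. The chemokine Ccl3 read 2.23, 0.78 and -0.56, its relative Ccl4 1.96, 0.61 and -1.50 and Myc -1.50, -1.38 and -3.70. Across genes, which are not independent, the ATMKO response at 6 h correlated with that of ATMWT cells at r = 0.801, with the ATMKO response at 3 h at 0.301 and with that at 24 h at 0.482.

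The genotypes were compared before and after stimulation in 1 sample each, with no test. Across probes, the 3 arrays of untreated ATMKO cells correlated with one another at r = 0.803, 0.815 and 0.975. With the untreated ATMWT array they correlated at 0.701, 0.808 and 0.820. The difference between untreated genotypes therefore cannot be told apart from that between repeats. Untreated ATMKO minus ATMWT values lay beyond 1 on the log2 scale for 485 of 22300 genes, 402 higher and 83 lower, and at 6 h of anti-IgM for 41 genes, 15 higher and 26 lower. Of single genes that the B cell receptor is known to induce, untreated ATMKO minus ATMWT values were, for Nr4a1 3.10, Egr2 2.43, Irf4 1.91, Ccl4 1.80, Cd69 1.79 and Myc 1.55, and others lay nearer to 0 or below it, with Egr1 at 0.20, Egr3 at 0.18, Ccl3 at 0.22 and Fos at -0.50. At 6 h the first 6 of these read 0.02, 0.10, 0.19, 0.26, -0.23 and -0.05. Atm read -0.76 untreated and -1.38 at 6 h. Immediate early genes had a median of 0.64 untreated and -0.01 at 6 h.

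One hypothesis was that some lymphoma lines carry a gain or loss of a whole chromosome, which would shift its genes together. The largest median difference from the other 8 lines was 0.1995 on the log2 scale, for 1299 genes of chromosome 1 in line 1004, where 72.6% of genes lay above 0. Of 180 pairs of line and chromosome, 4 lay beyond 0.1, the others being chromosome 14 in line 1004 (0.102), chromosome 16 in line 1013 (0.126) and chromosome 5 in line 1016 (0.1001). The bounds set in advance were above 0.2 for a gain and below 0.1 for none, and what an extra copy gives on these arrays was not measured. The value of 0.1995 leaves open whether line 1004 may carry extra copies of chromosome 1, perhaps in part of its cells.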
